A study of Mus musculus with 8 samples.

How the data were processed

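RNA sequencing was used to measure gene expression in CD4+ T cells taken from mouse spleen. A green fluorescent protein reporter of Foxp3, the transcription factor that defines regulatory T (Treg) cells, separated reporter-positive Treg cells from reporter-negative non-Treg cells. Per the labels, the monoclonal cells came from a NOD strain whose T cells carry a single αβ T cell receptor and which lacks a Rag gene, the recombinase needed to assemble receptors. The polyclonal cells came from NOD reporter mice with a diverse receptor repertoire. NOD mice develop autoimmune diabetes spontaneously. The 8 libraries fell into 4 groups of 2: monoclonal Treg, monoclonal non-Treg, polyclonal Treg and polyclonal non-Treg, with replicates called A and B. Strain, Rag genotype and receptor changed together, so no comparison between the mice separates them. Nothing in the labels says that the 2 libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

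Per the labels' protocols, messenger RNA was selected with poly-dT beads, strand information was kept, and single-end reads of 50 bp were produced on a HiSeq2500. The submitters' processing notes name CASAVA 1.8.2, FastQC 0.10.1, Trimmomatic 0.33, STAR 2.4.1a, HOMER 4.7, edgeR without a version, and the genome build mm9, without giving the role of each. The authors deposited 1 table of 24016 genes, each with 1 RefSeq transcript and its mm9 position, and the deposited values are CPM, reads per 1000000 reads assigned to the genes of the table. Each library summed to 1000000, and 100% of the values were whole multiples of the value of 1 read within 0.01 read, so whole reads were recovered. No per-sample column was left unused. How reads that match several genes were counted is not given in the sources used here. Genes with many near-identical copies were low (Gapdh lay between 3.44 and 9.40 CPM), and values of such genes are uncertain. Gene positions are those of the deposited table on mm9. The genome sequence of another build was not used here.

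The recovered totals ran from 14076330 reads in polyclonal Treg replicate A to 19722321 in polyclonal Treg replicate B. A count of 0 allows up to 3 reads, which corresponds to 0.152 to 0.213 CPM depending on the library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Folds against a group with 0 reads in both libraries are lower bounds computed from the mean floor of 3 reads per library.

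The design fixed before the data were examined named edgeR's quasi-likelihood test for counts. Because the deposited unit was CPM, the main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a mean-variance trend and a robust estimate of the spread. The pseudocount of 1 CPM understates the change of low genes. Genes with at least 1 CPM in at least 2 libraries were kept, which left 12881. A mean was fitted for each of the 4 groups over all 8 libraries (4 residual degrees of freedom, median prior degrees of freedom 10). All tests were 2-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 5 comparisons were Treg against non-Treg in monoclonal mice, the same in polyclonal mice, the difference of these 2 Treg effects, and monoclonal against polyclonal mice within Treg and within non-Treg cells. Errors of fold changes are standard errors (SE) and errors of CPM values are standard deviations (SD).

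The 28 gene lists were fixed before the data were examined: Treg signature, Treg-repressed, naive and quiescence, effector-memory, TCR-induced early response, co-inhibitory and anergy, IL-2 and STAT5 targets, NF-kB targets, Th1, Th2, Th17, Tfh, trafficking receptors, TCR complex and proximal signalling, cell cycle, type I interferon, glycolysis, stress and heat shock, lymphocyte development, and markers of B cells, plasma cells, CD8 T cells, NK cells, myeloid cells, dendritic cells, erythroid cells and platelets, stromal cells and sex-linked genes. Each was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 28 lists of a comparison, and members were counted after adjustment over all genes and over the list alone. With the estimated correlation, 8 list results held. In the polyclonal Treg effect these were Treg signature, Treg-repressed, naive and quiescence, cell cycle and NK cell markers, and in monoclonal against polyclonal Treg cells they were NK cell, myeloid and dendritic cell markers.

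Genes were named by a rule fixed before the data were examined. Among genes past the threshold, with a mean log2 level of at least 2, and with both libraries of a group above both of the other, it takes the 12 largest changes each way for each Treg effect and 8 for the other comparisons. The separation of libraries was not asked of the difference of the Treg effects. Symbols of unnamed loci were skipped, which removed 1 gene. The rule adds Foxp3, Il2ra, Ctla4, Ikzf2, Nrp1, Rag1 and Rag2, up to 4 members of each list described, and the 10 genes with the largest smaller change of the 2 Treg effects. A few genes that the rule takes are not reported here, although counts include them. The splits of the monoclonal non-Treg replicates, the fits of each Treg effect on its own 4 libraries and the count of genes that differ alike between replicates A and B were chosen after the values were seen. Which lists were described member by member in which comparison was chosen after the values were seen.

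The test was tried on simulated data with 200 changed genes. These had a mean log2 level of at least 2, means were otherwise equal between groups, and each gene's spread was the same in every group. The real libraries differed in far more genes and had unequal spread between groups, so the shares below need not hold for them. For the monoclonal Treg effect (12674 genes), 62% of genes changed by 1 on the log2 scale and 88% of those changed by 2 were recovered, and 23 of 173 calls were false, a larger share than the nominal threshold. For the polyclonal Treg effect (12650 genes) the shares were 62% and 91%, with 5 of 158 calls false. For the difference of the effects, changes simulated in monoclonal Treg libraries were recovered in 30% and 70% of genes with 18 of 118 calls false, and changes simulated in polyclonal Treg libraries in 25% and 78% with 11 of 114 calls false.

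Alternatives fixed before the data were examined were DESeq2 1.42.0 and limma-voom on recovered reads, RLE size factors, no filter, a filter of 5 CPM, a fit without the robust step, a fit of only the libraries compared, a replicate block, thinning to the smallest library, stricter thresholds, an estimated correlation for the lists, and leaving out each library in turn. Library totals without further factors, also fixed then, is the scaling of the main test. Alternatives chosen after seeing the data were TMM factors on the CPM, pseudocounts of 0.1 and 5 CPM, scaling to the mean log2 level of Cd3d, Cd3e, Cd3g and Cd247, and leaving out genes higher in monoclonal than in polyclonal non-Treg libraries. The edgeR test that the design had named was run with edgeR 4.0.16 on recovered reads, only as an alternative added after seeing the data. On recovered reads edgeR called 2587 genes for the monoclonal and 933 for the polyclonal Treg effect, 959 for their difference, 2629 for monoclonal against polyclonal Treg cells and 1982 for non-Treg cells.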

Results

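The deposited table gave gene expression in 8 libraries of spleen CD4+ T cells, 2 each of monoclonal Treg, monoclonal non-Treg, polyclonal Treg and polyclonal non-Treg cells. Depth was 15220596 and 17708028 reads in monoclonal Treg replicates A and B, 18033924 and 15504813 in monoclonal non-Treg, 14076330 and 19722321 in polyclonal Treg, and 15800704 and 15492330 in polyclonal non-Treg libraries. Across genes, the log2 levels of the 2 replicates correlated at 0.9643, 0.9849, 0.9776 and 0.9907 in these groups, in the same order, and genes are not independent replicates. The variance between replicates was 27.7, 15.9, 44.7 and 7.59 times that of counting alone, which sets aside only the same library sequenced again and does not tell separate preparations from separate animals. The first principal component carried 56.1% of the variance and separated monoclonal from polyclonal libraries, and the second carried 20.5% and separated Treg from non-Treg libraries. Rag1 measured 7.05 ± 0.0659 CPM (SD, n = 2) in monoclonal Treg and 6.12 ± 4.03 in monoclonal non-Treg libraries, against 0.583 ± 0.825 and 0.285 ± 0.403 in the polyclonal ones. Rag1 did not differ between Treg and non-Treg libraries in either kind of mouse (adjusted p = 0.728 and 0.901). Rag2 had a total of 1 read, in monoclonal non-Treg replicate A, too few for a comparison at this depth. The labels do not say which Rag gene is deleted or where, so these levels check neither label.

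The libraries also differed in transcripts of other cell types. Cd74, the invariant chain that chaperones class II molecules in antigen-presenting cells, measured 2676 and 2023 CPM in monoclonal Treg replicates A and B and 7342 and 8497 CPM in monoclonal non-Treg replicates, against 47.9 to 110 CPM in the 4 polyclonal libraries. Itgax, which encodes the dendritic cell integrin CD11c, measured 245 and 241 CPM in monoclonal Treg, 961 and 1234 CPM in monoclonal non-Treg, and 2.13 to 10.9 CPM in polyclonal libraries. S100a9, a calcium-binding protein abundant in neutrophils, measured 497 CPM in monoclonal Treg replicate A and 77.9 in B, 157 and 21.5 in monoclonal non-Treg replicates A and B, and under 1 CPM in each polyclonal library. Cd3e, a subunit of the T cell receptor complex, measured 454 and 406 CPM in monoclonal non-Treg replicates and 623 to 805 CPM in every other library. The ribosomal RNA precursor Rn45s, listed in the table despite poly-dT selection, measured 3404 and 2846 CPM in monoclonal Treg libraries and 1817 to 2597 CPM in the others.

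**Figure D1:**
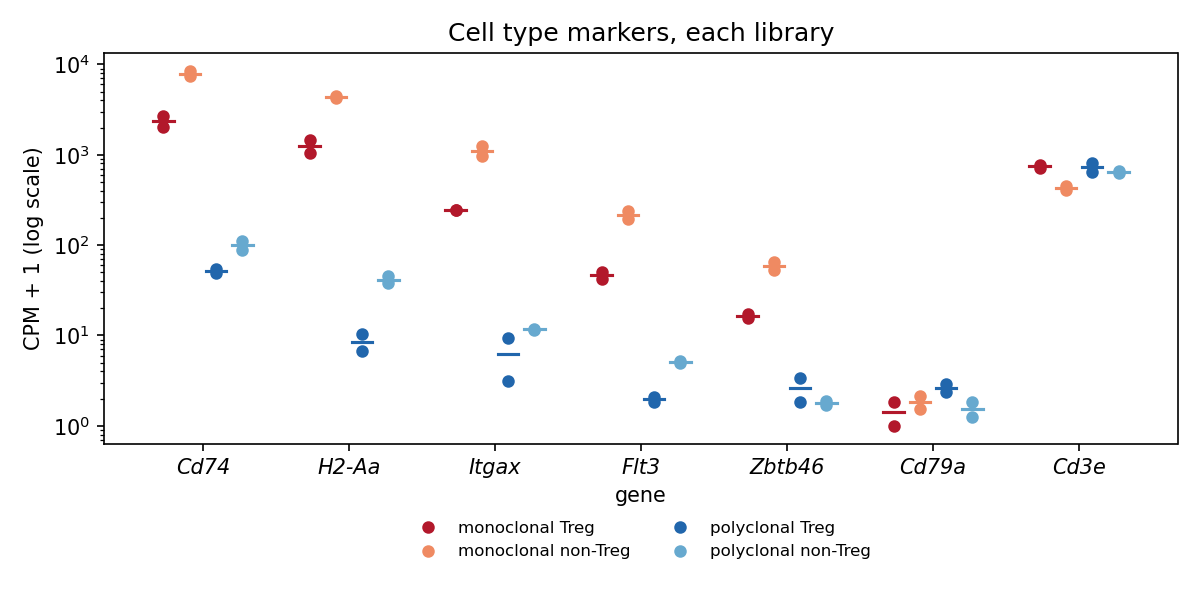
CPM + 1 on a log axis of 7 cell type markers in each library, with dots for the libraries and a dash for the mean of the 2. Cd74, H2-Aa, Itgax, Flt3 and Zbtb46 sit far higher in the monoclonal groups, highest in non-Treg libraries, while the B cell gene Cd79a stays at or below 1.16 CPM in them.

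The first question was how Treg cells differ from non-Treg cells when every T cell carries the same receptor. In monoclonal mice, genes of Treg identity were higher in Treg cells and genes of the naive T cell state were lower. Foxp3, the gene whose reporter was used to sort the cells (NM_001199347, chromosome X, 7156802 to 7172369 on mm9), measured 2688 ± 30.2 CPM in Treg and 362 ± 60.8 CPM in non-Treg libraries (SD, n = 2 each), a log2 fold change of 2.90 ± 0.12 (adjusted p = 4.59e-09). Il2ra, the high-affinity interleukin-2 receptor chain (chromosome 2, 11564419 to 11614821), rose from 71.7 ± 30.5 to 514 ± 74.3 CPM. Ctla4, an inhibitory receptor through which Treg cells restrain antigen-presenting cells (chromosome 1, 60965869 to 60972676), rose by 2.90 ± 0.13 on the log2 scale, and the transcription factor Ikzf2 (chromosome 1, 69577784 to 69732534) by 2.88 ± 0.13. Klrg1, a receptor of highly differentiated lymphocytes, reached 551 ± 1.74 CPM against 66.1 ± 29.8, and Il1rl1, the interleukin-33 receptor found on tissue Treg cells, reached 1356 ± 30.4 CPM against 191 ± 60.3.

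Of the Treg signature, 26 of 32 genes were higher in monoclonal Treg cells and 1 was lower (28 and 2 when adjusted over the list alone). The median log2 fold change was 2.15 (camera, adjusted p = 2.32e-21; adjusted p = 0.0814 with an estimated correlation). Nrp1, a receptor common on thymus-derived Treg cells, rose by 1.91 ± 0.17, and Nt5e, an enzyme that makes adenosine, by 2.56 ± 0.16. Of 25 effector-memory genes, 14 were higher and 1 lower (16 and 1 adjusted over the list alone). The median was 1.03 (camera, adjusted p = 6.29e-09; adjusted p = 0.302 with an estimated correlation). Among them were the transcription factor Maf at 2.96 ± 0.16, the chemokine receptor Ccr2 at 1.86 ± 0.15 and the integrin Itgb1 at 1.55 ± 0.12. The largest increases also took in Lrrc32, which displays latent TGF-β on Treg cells, Bicd1, the cytokine signalling inhibitor Socs2, Rln3 and the chemokine receptor Ccr3, with log2 fold changes of 2.87 to 3.06.

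Genes of naive T cells fell. Of 19 naive and quiescence genes, 12 were lower and 2 higher in monoclonal Treg cells (12 and 5 adjusted over the list alone). The median was -1.13 (camera, adjusted p = 4.38e-07; adjusted p = 0.0814 with an estimated correlation). Tcf7, a transcription factor of naive and stem-like T cells, fell by 3.19 ± 0.13 on the log2 scale from 1271 ± 166 CPM in non-Treg libraries. Ccr7, which guides cells into lymph nodes, went from 370 ± 55.5 to 39.7 ± 4.56 CPM. Of 16 Treg-repressed genes tested, 11 were lower and 2 higher (12 and 2 adjusted over the list alone). The median was -2.34 (camera, adjusted p = 1.03e-07; adjusted p = 0.0814 with an estimated correlation). Igfbp4 fell by 4.06 ± 0.17, the chromatin organiser Satb1 by 2.76 ± 0.15, and Actn1 went from 226 ± 19.2 to 39.7 ± 10.1 CPM. The largest decreases also held Pdlim4, Vipr1, Rapgef4, Slc16a5, Nsg2, the interleukin-1 receptor Il1r1, Dzip1 and Adam11, with log2 fold changes from -4.15 to -3.23, and Dapl1, which went from 89.0 ± 17.0 to 4.51 ± 3.68 CPM. Tns4 and Lypd6b had no reads in either monoclonal Treg library and were at least 131-fold and 84.5-fold lower there.

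Transcripts of genes switched on within minutes of receptor signalling were lower in monoclonal Treg than in monoclonal non-Treg libraries. Of 23 TCR-induced early response genes, 11 were lower and 4 higher (11 and 5 adjusted over the list alone). The median was -0.43 (camera, adjusted p = 0.0243; adjusted p = 0.461 with an estimated correlation). Egr1, an immediate early transcription factor, went from 1690 ± 70.1 to 484 ± 27.3 CPM and Fosb from 1045 ± 172 to 220 ± 17.4 CPM, and Egr2 and Egr3 fell by 2.11 ± 0.21 and 1.94 ± 0.20. Egr1, Fosb, Egr2 and Egr3 measured 104, 28.7, 31.6 and 49.8 CPM in polyclonal non-Treg libraries and 1690, 1045, 63.2 and 57.6 CPM in monoclonal ones. Markers of other cells moved the same way, and which cells gave the early response transcripts was not tested. Of 9 dendritic cell markers, 7 were lower in Treg libraries (8 adjusted over the list alone), among them Flt3 at -2.22 ± 0.26, Siglech at -2.45 ± 0.43, Batf3 at -2.13 ± 0.39 and Ccr9 at -1.84 ± 0.29, and the median was -2.07 (camera, adjusted p = 0.000105; adjusted p = 0.0814 with an estimated correlation). Of 13 B cell list genes tested, 10 were lower, the same number adjusted over the list alone. The median was -1.81 (camera, adjusted p = 2.15e-07; adjusted p = 0.302 with an estimated correlation). The class II genes Cd74, H2-Eb1 and H2-Aa fell by 1.76 to 1.87 and Cd22 fell by 2.21. The early response call was lost without monoclonal non-Treg replicate A (adjusted p = 0.0621), and the Siglech call in a fit of only the libraries compared (adjusted p = 0.141).

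In the monoclonal Treg comparison, 3143 of 12881 genes differed (limma, adjusted p under 0.05), 1396 higher and 1747 lower in Treg cells, of which 643 and 1131 changed at least 2-fold. The overlap with genes higher in monoclonal than in polyclonal non-Treg cells was taken from mean differences, with the monoclonal non-Treg replicates split so that no library was shared. With replicate A in the Treg effect and B in the other comparison, 53.6% of the 1512 genes at least 2-fold higher in monoclonal non-Treg cells were at least 2-fold lower in Treg cells, against 5.32% of the other genes. With the replicates exchanged, the shares were 57.9% of 1481 genes and 5.99%. Scaled to the CD3 genes, which shifted the median of all genes by -0.46 on the log2 scale, 422 genes were higher and 3106 lower, 12% higher against 44.4% in the main test. The count was 1879 without monoclonal non-Treg replicate A, 1306 without replicate B, and 2003 when genes higher in monoclonal than in polyclonal non-Treg libraries, a choice that shares the non-Treg libraries, were left out.

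**Figure D2:**
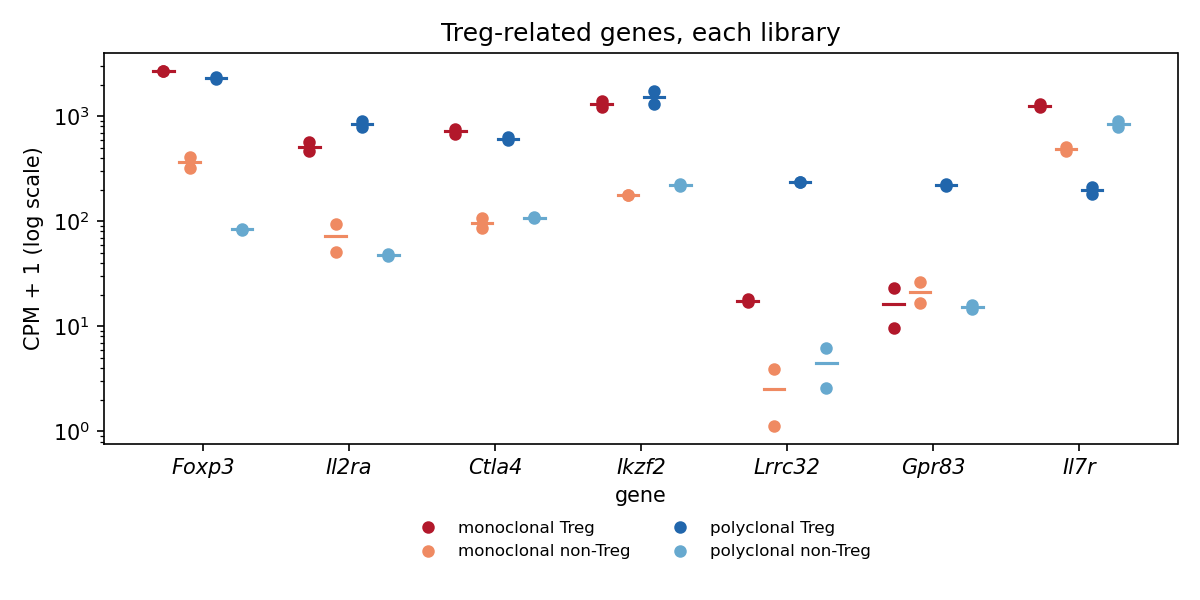
CPM + 1 on a log axis of 7 Treg-related genes in each library, with dots for the libraries and a dash for the mean of the 2. Foxp3 lies near 2688 and 2316 CPM in the Treg groups and at 362 and 83.1 CPM in the non-Treg groups, and Il7r and Gpr83 separate the groups differently in monoclonal and polyclonal mice.

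The polyclonal mice gave the same contrast in cells with many receptors. Treg identity genes were again higher, together with NF-kB targets, interleukin-2 response genes and cell cycle genes, and naive T cell genes were lower. Foxp3 measured 2316 ± 48.1 CPM in Treg and 83.1 ± 1.65 CPM in non-Treg libraries (SD, n = 2 each), a log2 fold change of 4.78 ± 0.12 (adjusted p = 1.37e-11). Il2ra rose by 4.14 ± 0.21, Ikzf2 by 2.75 ± 0.13 and Nrp1 by 1.66 ± 0.17, and Ctla4 went from 107 ± 1.89 to 611 ± 29.1 CPM. Lrrc32 (chromosome 7, 105642732 to 105650340) showed the largest increase, from 3.43 ± 2.57 to 234 ± 0.367 CPM, and Gpr83, a G protein-coupled receptor of Treg cells, rose from 14.2 ± 0.841 to 221 ± 9.32 CPM. Ikzf4, a relative of Ikzf2, rose by 4.06 ± 0.17, and Cybrd1, Fsd1l, Ppp1r3fos, Arhgap20, Stra6, Capn3 and the integrin Itgae rose by 3.44 to 4.73.

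Of the Treg signature, 29 of 32 genes were higher and 0 lower by limma (31 and 0 adjusted over the list alone). The median log2 fold change was 2.30 (camera, adjusted p = 6.05e-53; adjusted p = 0.0274 with an estimated correlation). Of 15 NF-kB targets, 12 were higher (13 adjusted over the list alone). The median was 0.68 (camera, adjusted p = 1.05e-14; adjusted p = 0.0623 with an estimated correlation). Cd83, a surface marker of activation, rose by 3.06 ± 0.21, the survival gene Bcl2l1 by 1.48 ± 0.21, the adhesion molecule Icam1 by 1.08 ± 0.16 and Nfkb2 by 0.96 ± 0.14. Of 16 IL-2 and STAT5 targets, 9 were higher and 1 lower (10 and 1 adjusted over the list alone), including Cish at 2.26 ± 0.16, Il2rb at 1.79 ± 0.15 and Tnfrsf18 at 1.74 ± 0.22 (camera, adjusted p = 3.95e-10; adjusted p = 0.0762 with an estimated correlation). Of 18 co-inhibitory and anergy genes, 9 were higher, the same number adjusted over the list alone, with Tigit at 2.01 ± 0.21 and the folate receptor family member Folr4 at 1.96 ± 0.21 (camera, adjusted p = 8.13e-08; adjusted p = 0.0876 with an estimated correlation). Of 27 cell cycle genes, 9 were higher (17 adjusted over the list alone). The median was 0.83 (camera, adjusted p = 1.70e-10; adjusted p = 0.0354 with an estimated correlation).

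The cell cycle genes named by the rule were the proliferation marker Mki67 at 0.77 ± 0.14, Tk1 at 1.30 ± 0.28, the topoisomerase Top2a at 0.90 ± 0.20 and Ccna2 at 1.16 ± 0.27. Without polyclonal non-Treg replicate A the adjusted p was 0.0520 for Mki67, 0.0819 for Tk1, 0.148 for Top2a and 0.241 for Ccna2, without replicate B it was 0.0540, 0.117 and 0.0515 for the first 3, and without polyclonal Treg replicate B it was 0.0854 for Ccna2. Scaled to the CD3 genes, Mki67 and Top2a changed by 0.83 and 0.96, no less than in the main test, with adjusted p of 0.129 and 0.0684. Top2a had 0.0699 with no filter and Ccna2 had 0.0609 in a fit of only the polyclonal libraries. Of 19 naive and quiescence genes, 11 were lower and 0 higher by limma (11 and 1 adjusted over the list alone). The median was -0.52 (camera, adjusted p = 1.50e-11; adjusted p = 0.0354 with an estimated correlation). Il7r, the interleukin-7 receptor that sustains naive and memory T cells, went from 848 ± 79.0 CPM in non-Treg to 196 ± 22.2 CPM in Treg libraries, and Tcf7 and its relative Lef1 fell by 1.29 ± 0.13 and 1.08 ± 0.13. Of 16 Treg-repressed genes tested, 10 were lower and 1 higher (13 and 1 adjusted over the list alone). The median was -1.34 (camera, adjusted p = 1.20e-16; adjusted p = 0.0215 with an estimated correlation). The phosphodiesterase Pde3b fell by 3.52 ± 0.39, Igfbp4 by 2.59 ± 0.17 and Dapl1 by 3.73 ± 0.41. The other large decreases were Pdlim4, Ggt5, Adamts14, Lrrc75b, Vipr1, the amyloid precursor gene App, Atp8b4, Lypd6b and Tdrp, with log2 fold changes from -4.54 to -2.98.

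Markers of other cell types were low and still moved. Of 9 NK cell markers tested, 3 were lower in polyclonal Treg libraries (6 adjusted over the list alone). The median was -1.20 (camera, adjusted p = 1.60e-06; adjusted p = 0.0354 with an estimated correlation). Of 9 dendritic cell markers, 2 were lower (4 adjusted over the list alone). The median was -0.83, or -1.10 with the members that had no reads in Treg libraries set at their bounds (camera, adjusted p = 0.000972; adjusted p = 0.0762 with an estimated correlation). In all, 1018 of 12881 genes differed (limma), 596 higher and 422 lower in Treg cells, of which 374 and 236 changed at least 2-fold. The count was 469 without polyclonal non-Treg replicate A, 429 without replicate B, 553 scaled to the CD3 genes and 673 in a fit of only the polyclonal libraries.

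Both Treg effects shared a set of genes. In the same direction in both kinds of mice, 272 genes were higher and 243 lower in Treg cells, where independent lists of these sizes would share 64.6 and 57.2. In opposite directions were 89 genes, where independent lists would share 127. Both effects took their spread from all 8 libraries, so these lists are not independent. With each effect fitted on its own 4 libraries, 187 genes were higher and 163 lower in both, against 42.7 and 34.2 for independent lists, and 48 went opposite ways against 79.8. Across the 12881 genes the 2 log2 fold changes correlated with Pearson's r of 0.317 and Spearman's rho of 0.231, and genes are not independent replicates. Among the genes changed most in both, Klrg1 rose by 3.12 ± 0.28 in monoclonal and 3.34 ± 0.28 in polyclonal mice, and Lrrc32, Foxp3 and Il2ra rose by at least 2.88 in each. Pdlim4 fell in both, at -4.15 ± 0.47 and -4.54 ± 0.47. Vipr1, a receptor of vasoactive intestinal peptide, went from 154 ± 6.92 to 8.79 ± 1.94 CPM in monoclonal and from 279 ± 23.2 to 24.0 ± 6.38 CPM in polyclonal mice, and Dapl1 fell alongside. Slc6a7 had no reads in monoclonal Treg libraries and was at least 95.8-fold lower there, and Ggt5 and Lypd6b also fell in both. The count of 515 shared genes was 334 without monoclonal non-Treg replicate B, 288 and 267 without polyclonal non-Treg replicates A and B, and 267 scaled to the CD3 genes.

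The study's second question set the monoclonal Treg effect against the polyclonal one, and the difference of the 2 effects was tested directly. Genes of effector and memory cells had a higher Treg effect in monoclonal than in polyclonal mice, while naive, NF-kB and early response genes had a lower one. In polyclonal Treg cells, 7 of 25 effector-memory genes were lower and 3 higher (8 and 4 adjusted over the list alone). Their median there was -0.23 (camera, adjusted p = 0.0523; adjusted p = 0.617 with an estimated correlation). Il7r was higher in Treg cells of monoclonal mice (1253 ± 57.4 against 487 ± 33.6 CPM, SD, n = 2) and lower in Treg cells of polyclonal mice (196 ± 22.2 against 848 ± 79.0 CPM), a difference of 3.47 ± 0.17 on the log2 scale (adjusted p = 1.39e-07). Cd83 went the opposite way, lower in monoclonal Treg libraries (27.3 ± 3.43 against 79.1 ± 4.93 CPM) and higher in polyclonal Treg libraries (148 ± 39.0 against 16.6 ± 3.21 CPM). The difference was -4.57 ± 0.30 (limma, adjusted p = 1.83e-06), and which cells gave Cd83 in the monoclonal libraries was not tested. The Foxp3 effect was smaller in monoclonal mice by -1.89 ± 0.17, with non-Treg levels of 362 ± 60.8 CPM in monoclonal and 83.1 ± 1.65 CPM in polyclonal libraries. Gpr83 rose in polyclonal Treg cells and measured 15.5 ± 9.64 CPM in Treg against 20.4 ± 6.93 CPM in non-Treg libraries of monoclonal mice, a difference of -4.35 ± 0.47.

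Of 25 effector-memory genes, the Treg effect was higher in monoclonal mice for 16 and lower for 0 by limma (18 and 0 adjusted over the list alone). The median difference was 1.27 (camera, adjusted p = 8.73e-16; adjusted p = 0.289 with an estimated correlation). Ccr2 differed by 2.57 ± 0.22, Lgals3, a galectin of activated and myeloid cells, by 2.46 ± 0.37, Maf by 2.35 ± 0.22 and Itgb1 by 1.8 ± 0.17. Of 19 naive and quiescence genes it was lower for 10 and higher for 3 (11 and 4 adjusted over the list alone). The median was -0.88 (camera, adjusted p = 0.00157; adjusted p = 0.289 with an estimated correlation). Examples were Ccr7 at -2.29 ± 0.24 and Tcf7 at -1.90 ± 0.18. Of 15 NF-kB targets it was lower for 10 and higher for 2, the same numbers adjusted over the list alone. The median was -1.01 (camera, adjusted p = 0.000441; adjusted p = 0.289 with an estimated correlation). Examples were the subunits Rel at -1.88 ± 0.25 and Relb at -1.71 ± 0.28 and the adaptor Traf1 at -1.19 ± 0.16. Of 23 early response genes it was lower for 9 and higher for 1 (11 and 3 adjusted over the list alone). The median was -0.64 (camera, adjusted p = 0.00157; adjusted p = 0.289 with an estimated correlation). Examples were Egr2 at -3.00 ± 0.30, Nr4a1 at -2.75 ± 0.24, Egr3 at -2.56 ± 0.28 and Egr1 at -2.16 ± 0.20. Class II and dendritic cell transcripts were higher in monoclonal non-Treg than in monoclonal Treg libraries, as given above. Whether T cells or other cells gave the lower NF-kB and early response effects was not tested. Of 13 B cell list genes the Treg effect was lower for 3 (7 adjusted over the list alone). The median was -1.20 (camera, adjusted p = 0.00157; adjusted p = 0.384 with an estimated correlation).

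Besides Il7r, the largest positive differences were in Mtus1 at 4.21 ± 0.54, the cytokine receptors Il9r at 3.46 ± 0.25 and Il17rb at 3.36 ± 0.51, and Adamts14, Klra1, Nmnat2 and Popdc2 between 3.03 and 3.32. The largest negative ones besides Cd83 and Gpr83 were in the iron reductase Cybrd1 at -5.91 ± 0.80, Cdhr3 at -5.26 ± 0.52, and Gucy1a3, Zfp608, Pla2g4f and Igsf3 between -4.72 and -4.41. Ctla4, Ikzf2 and Nrp1 had differences of 0.40 ± 0.18, 0.13 ± 0.19 and 0.24 ± 0.24 that did not pass the test (adjusted p = 0.206, 0.743 and 0.606) and that turned negative when scaled to the CD3 genes, at -0.14, -0.41 and -0.29. Without polyclonal Treg replicate B the Ikzf2 difference was -0.07, and without monoclonal non-Treg replicate B that of Nrp1 was -0.02. Il2ra differed by -1.25 ± 0.30 (adjusted p = 0.0188), with an adjusted p of 0.0857 without monoclonal Treg replicate B, 0.0720 without monoclonal non-Treg replicate A, 0.114 and 0.0799 without polyclonal Treg replicates A and B, 0.0747 and 0.0629 without polyclonal non-Treg replicates A and B, and 0.0980 with no filter. Klra1 lost its call without monoclonal non-Treg replicate A or B (adjusted p = 0.0674 and 0.0599) or polyclonal non-Treg replicate B (0.0656), with no filter (0.0565) and with edgeR (0.0567). Nmnat2 lost it without monoclonal non-Treg replicate B (0.0536), Popdc2 with limma-voom (0.0702) and Cybrd1 with DESeq2 (0.0638).

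The 2 Treg effects differed in 1185 of 12881 genes (limma), 469 higher and 716 lower in monoclonal mice. Of these, 473 fell in monoclonal Treg cells without passing the test in polyclonal mice, and 322 rose in monoclonal Treg cells without passing it in polyclonal mice. A further 95 rose in polyclonal Treg cells without passing the test in monoclonal mice, and 66 fell in monoclonal and rose in polyclonal Treg cells. Scaled to the CD3 genes, which shifted the median of all genes by -0.52, 80 genes were higher and 1203 lower, 6.24% higher against 39.6% in the main test. The count was 579 and 361 without monoclonal non-Treg replicates A and B, 547 and 490 without polyclonal non-Treg replicates A and B, 756 with no filter, and 548 when genes higher in monoclonal than in polyclonal non-Treg libraries were left out.

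**Figure D3:**
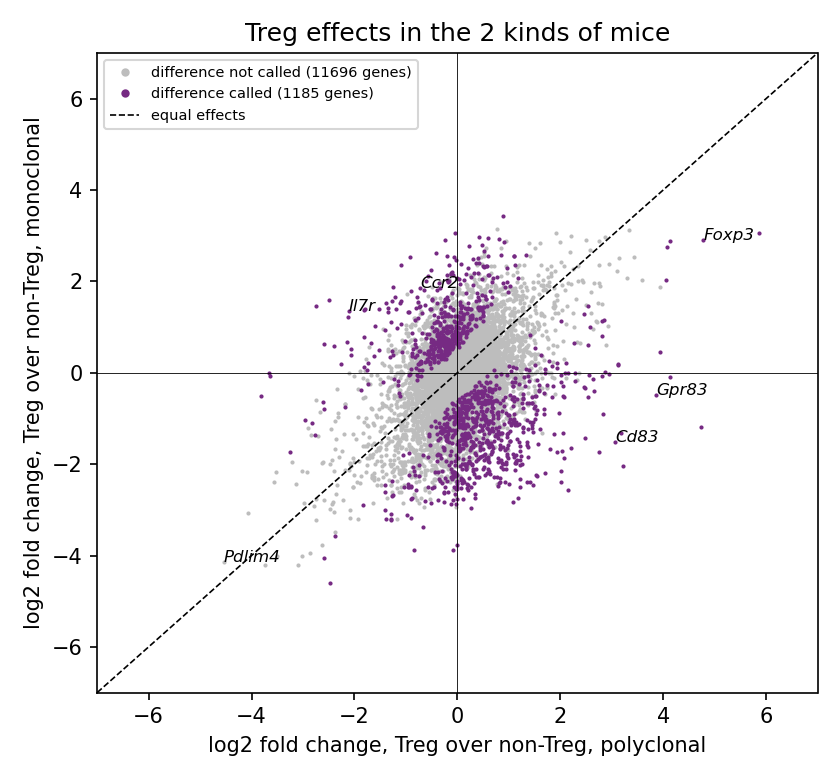
Each dot is a gene, placed by its log2 fold change of Treg over non-Treg cells in polyclonal mice (horizontal) and in monoclonal mice (vertical). Purple marks the 1185 genes whose effects differed by limma, grey the others, and the dashed line marks equal effects.

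Monoclonal and polyclonal Treg cells were also compared directly. Foxp3, Ctla4, Ikzf2 and Nrp1 did not differ by the test, while other Treg signature genes went both ways. Monoclonal Treg libraries held more effector-memory transcripts, fewer naive and cell cycle transcripts, and many transcripts of myeloid and dendritic cells. Foxp3 differed by 0.22 ± 0.12 (adjusted p = 0.228), Ctla4 by 0.23 ± 0.13, Ikzf2 by -0.20 ± 0.13 and Nrp1 by -0.19 ± 0.17, none of which passed the test. The call of Ikzf2 changed without polyclonal Treg replicate B (-0.39, adjusted p = 0.0146). Il2ra was lower in monoclonal Treg cells by -0.72 ± 0.21 (adjusted p = 0.0251), with adjusted p of 0.170 without monoclonal Treg replicate B, 0.217 and 0.103 without polyclonal Treg replicates A and B, 0.0795 scaled to the CD3 genes and 0.1 with no filter. Of the 32 Treg signature genes, 9 were higher and 11 lower (10 and 11 adjusted over the list alone), including Lrrc32 at 16.5 ± 0.772 against 234 ± 0.367 CPM and Gpr83 at 15.5 ± 9.64 against 221 ± 9.32 CPM. The median was -0.21 (camera, adjusted p = 0.469). Rag1 was higher by 2.45 ± 0.52 (adjusted p = 0.00334), and its call was lost with edgeR and limma-voom (adjusted p = 0.0812 and 0.0531).

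Of 25 effector-memory genes, 16 were higher and 1 lower in monoclonal Treg cells (17 and 1 adjusted over the list alone). The median was 1.17 (camera, adjusted p = 1.42e-09; adjusted p = 0.223 with an estimated correlation). Klrg1 measured 551 ± 1.74 against 32.1 ± 7.78 CPM and Ccr2 721 ± 67.6 against 50.2 ± 3.95 CPM, and Lgals3 and the calcium-binding protein S100a6 rose by 3.68 ± 0.26 and 2.69 ± 0.20. In monoclonal non-Treg libraries Klrg1, Ccr2, Lgals3 and S100a6 measured 66.1, 201, 75.1 and 117 CPM. Lgals3 was thus almost as high there as in monoclonal Treg libraries (86.2 CPM). Myeloid markers were also higher in monoclonal Treg libraries, and their cells' share in the effector-memory transcripts was not tested. Of 19 naive and quiescence genes, 12 were lower and 4 higher (12 and 6 adjusted over the list alone). The median was -0.70 (camera, adjusted p = 0.00141; adjusted p = 0.159 with an estimated correlation). Bach2, a repressor of effector programmes, fell by 3.16 ± 0.22, Tcf7 fell as well, and Il7r rose by 2.67 ± 0.12. Of 27 cell cycle genes, 14 were lower (20 adjusted over the list alone). The median was -0.84 (camera, adjusted p = 3.51e-07; adjusted p = 0.0674 with an estimated correlation). Examples were Mki67 at -1.31 ± 0.14, Top2a at -1.35 ± 0.20 and Rrm2 at -1.27 ± 0.26, and the replication helicase subunit Mcm5 fell from 108 ± 26.3 to 53.0 ± 6.87 CPM. Of 9 follicular helper (Tfh) genes tested, 7 were lower, the same number adjusted over the list alone. The median was -1.05, or -1.10 with a member at its bound (camera, adjusted p = 1.19e-05; adjusted p = 0.0674 with an estimated correlation). The follicle homing receptor Cxcr5 fell by 3.27 ± 0.25, Pou2af1 by 3.08 ± 0.50, Tnfsf8 by 2.56 ± 0.30 and the transcription factor Bcl6 by 1.10 ± 0.18. With DESeq2 the adjusted p of Pou2af1 was 0.171.

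Of 20 myeloid markers, 14 were higher in monoclonal Treg libraries, the same number adjusted over the list alone. The median was 2.67 (camera, adjusted p = 1.80e-11; adjusted p = 0.0473 with an estimated correlation). Examples were Itgax at 5.49 ± 0.37, the transcription factor Spi1 at 4.52 ± 0.30, Itgam at 4.06 ± 0.40 and Clec4a1 at 3.87 ± 0.36. Of 9 dendritic cell markers, 7 were higher (9 adjusted over the list alone). The median was 2.91, or 4.30 with members at their bounds (camera, adjusted p = 4.21e-08; adjusted p = 0.0473 with an estimated correlation). The cytokine receptor Flt3 rose by 4.57 ± 0.26, Siglech by 4.30 ± 0.43, and Batf3 was at least 59.1-fold higher. Of 9 NK cell markers tested, 7 were higher (8 adjusted over the list alone). The median was 3.33, or 3.39 with a member at its bound (camera, adjusted p = 4.61e-07; adjusted p = 0.0473 with an estimated correlation). The members named were the adaptors Tyrobp at 4.68 ± 0.28 and Fcer1g at 4.66 ± 0.45, which myeloid cells also use, and the receptors Klrd1 at 4.06 ± 0.29 and Klrk1 at 3.33 ± 0.36. The largest increases were in H2-Aa, H2-Ab1 and H2-Eb1, between 6.73 and 7.19, Il1b and Rnd3, and the neutrophil genes Ngp, S100a9 and S100a8. The neutrophil genes differed between the monoclonal Treg replicates, with Ngp at 352 CPM in A and 56.0 CPM in B. Without polyclonal Treg replicates A and B the adjusted p was 0.0586 and 0.0662 for S100a9 and 0.0875 and 0.0868 for S100a8, and with limma-voom it was 0.656 for Ngp, 0.597 for S100a9, 0.672 for S100a8 and 0.110 for Siglech. S100a8 also lost its call with edgeR (0.0565) and a pseudocount of 5 CPM (0.0746).

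The largest decreases in monoclonal Treg libraries were in Igj, the joining chain of secreted antibodies (0.225 ± 0.239 against 96.4 ± 48.0 CPM), Npas4, an activity-induced transcription factor, Hdgfrp3, the calcium channel Ryr2, Nr4a3 and Hivep3, with log2 fold changes from -6.23 to -4.42. Slc7a10 and Gucy1a3 had no reads in monoclonal Treg libraries and were at least 287-fold and 157-fold lower. In all, 3116 of 12881 genes differed (limma), 1553 higher and 1563 lower in monoclonal Treg cells, of which 1028 and 687 changed at least 2-fold. The count was 1796 scaled to the CD3 genes and 1721 in a fit of only the Treg libraries. The main test shares its spread over all groups. The median absolute log2 difference between replicates was 0.273 and 0.295 in monoclonal and polyclonal Treg libraries. In the non-Treg libraries it was 0.189 and 0.15. The shared spread may therefore be too small for this comparison, and its adjusted p-values too low.

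The last comparison set monoclonal against polyclonal non-Treg cells. Monoclonal non-Treg libraries held far more transcripts of antigen-presenting cells, more NF-kB, early response and interferon transcripts, and fewer transcripts of the T cell receptor complex and of follicular helper cells. H2-Aa measured 4367 ± 210 CPM against 40.5 ± 5.13 CPM (SD, n = 2 each), a log2 fold change of 6.72 ± 0.19 (adjusted p = 2.28e-11), and Cd74 rose by 6.32 ± 0.15. Of 9 dendritic cell markers, 8 were higher, the same number adjusted over the list alone. The median was 4.41 (camera, adjusted p = 4.44e-10; adjusted p = 0.0669 with an estimated correlation). Examples were Itgax at 6.54 ± 0.37, Flt3 at 5.41 ± 0.26 and the dendritic cell transcription factors Zbtb46 at 5.03 ± 0.37 and Batf3 at 4.56 ± 0.39. Of 20 myeloid markers, 13 were higher, the same number adjusted over the list alone. The median was 3.35, or 3.77 with a member at its bound (camera, adjusted p = 4.01e-11; adjusted p = 0.0713 with an estimated correlation). Examples were Clec4a1, the macrophage marker Emr1, Spi1 and the growth factor receptor Csf1r between 4.65 and 5.67. Of 13 B cell list genes tested, 11 were higher, the same number adjusted over the list alone. The median was 2.82 (camera, adjusted p = 6.32e-12; adjusted p = 0.136 with an estimated correlation), and the members named, Cd74, H2-Aa, H2-Ab1 and H2-Eb1, are class II genes that dendritic cells also use. The other 7 higher members are not these genes. Among them, Cd22 at 223 against 51.8 CPM and Blk at 27.3 against 2.94 CPM were picked after their values were seen. Foxp3 was higher in monoclonal non-Treg cells by 2.10 ± 0.12 (adjusted p = 1.31e-08).

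Of 23 TCR-induced early response genes, 13 were higher and 5 lower in monoclonal non-Treg cells (13 and 6 adjusted over the list alone). The median was 0.98 (camera, adjusted p = 1.53e-05; adjusted p = 0.136 with an estimated correlation). Fosb rose by 5.13 ± 0.19, Egr1 by 4.02 ± 0.14, Fos by 3.89 ± 0.17 and Nr4a1 by 3.22 ± 0.17. Of 15 NF-kB targets, 12 were higher, the same number adjusted over the list alone. The median was 0.79 (camera, adjusted p = 1.78e-08; adjusted p = 0.136 with an estimated correlation). Examples were Cd83 at 2.19 ± 0.21, Relb at 2.04 ± 0.19, Icam1 at 1.70 ± 0.16 and the feedback inhibitor Tnfaip3 at 1.37 ± 0.15. Of 26 type I interferon genes, 13 were higher (15 adjusted over the list alone). The median was 0.91 (camera, adjusted p = 1.09e-05; adjusted p = 0.189 with an estimated correlation). Examples were Bst2 at 2.09 ± 0.24, Mx1 at 1.72 ± 0.26, Oas2 at 1.51 ± 0.19 and Stat2 at 0.95 ± 0.13. Dendritic cell and class II transcripts were higher in these libraries, as given above. Of 16 genes of the TCR complex and proximal signalling, 12 were lower (15 adjusted over the list alone). The median was -0.64 (camera, adjusted p = 1.14e-08; adjusted p = 0.121 with an estimated correlation). The list holds the 4 genes of the CD3 scaling, and the other 12 had a median of -0.78, or -0.29 after that scaling. The costimulatory receptor Cd28 fell by 1.69 ± 0.13, the adaptor Lat by 0.98 ± 0.13, the kinase Zap70 by 0.95 ± 0.12 and Plcg1 by 0.92 ± 0.11, and Lat, Zap70 and Plcg1 lost their calls after CD3 scaling (adjusted p = 0.158, 0.192 and 0.270).

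Of 9 Tfh genes tested, 7 were lower (8 adjusted over the list alone). The median was -1.76, or -2.02 with members at their bounds (camera, adjusted p = 1.53e-05; adjusted p = 0.0948 with an estimated correlation). Il21, the cytokine of follicular helper cells, had no reads in monoclonal non-Treg libraries and 21.2 ± 1.88 CPM in polyclonal ones, at least 118-fold lower, and Cxcr5, Pdcd1 and Cd200 fell by 2.19 ± 0.25, 2.02 ± 0.35 and 1.76 ± 0.17. Pdcd1 had an adjusted p of 0.0896 with limma-voom. The largest increases besides class II genes were in the stress-induced transcription factor Atf3 at 7.25 ± 0.35, Rnd3, Stra6l, the inflammatory cytokine Il1b at 6.95 ± 0.33 and Plbd1. The largest decreases were in Igj, Angptl2, Cpne7, the growth factor receptor inhibitor Lrig1, Synpo, Npas4, the cytokine Ifng and Slc7a10, with log2 fold changes from -5.57 to -2.94. Il2ra, Ctla4, Ikzf2 and Nrp1 differed by 0.54 ± 0.21, -0.17 ± 0.13, -0.33 ± 0.13 and -0.44 ± 0.17 and did not pass the test, and after CD3 scaling the last 3 were positive, at 0.32, 0.16 and 0.04, and still did not pass, while Il2ra passed at 1.02 (adjusted p = 0.0136). Il2ra also passed with DESeq2 (0.68, adjusted p = 0.0122), and Ikzf2 and Nrp1 passed in a fit of only the non-Treg libraries (adjusted p = 0.00693 and 0.0299). Leaving out a library changed further calls: Il2ra passed without monoclonal non-Treg replicate B (adjusted p = 0.00357), Nrp1 without replicate A (0.0301), and Ikzf2 without either polyclonal Treg library (0.0143 and 0.0135). Rag1 was higher by 2.38 ± 0.52 (adjusted p = 0.00405), with adjusted p of 0.107 without monoclonal non-Treg replicate B, 0.0661 without polyclonal non-Treg replicate B, 0.0552 with edgeR and 0.0813 with limma-voom.

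In all, 2505 of 12881 genes differed between monoclonal and polyclonal non-Treg cells (limma), 1558 higher and 947 lower in monoclonal mice, of which 1243 and 238 changed at least 2-fold. Of the genes past the threshold, 787 were higher and 378 lower in both Treg and non-Treg cells of monoclonal mice, where independent lists would share 188 and 115, and 85 went opposite ways, where they would share 303. The spread of both comparisons came from the same 8 libraries, so these lists are not independent. Scaled to the CD3 genes, which shifted the median of all genes by 0.47, 2395 genes were higher and 125 lower, 95% higher against 62.2% in the main test. The count was 1627 and 1373 without monoclonal non-Treg replicates A and B, 1426 and 1409 without polyclonal non-Treg replicates A and B, and 4413 in a fit of only the non-Treg libraries.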

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

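The planned comparison here was the difference of the 2 Treg effects, tested with limma in place of the edgeR test that the design had named. The tests in the weighing of the effector-memory genes were chosen only after the result was seen. The difference of the effects passed for 1185 of 12881 genes by limma, and edgeR on recovered reads called 959. Of the genes named for either Treg effect or their difference, 50 reported here passed, 35 with a lower and 15 with a higher effect in monoclonal mice, with adjusted p between 1.39e-07 and 0.0397. What drew attention to each was this difference between the mice in the same contrast.

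Below -4, the difference was -5.91 for Cybrd1, -5.26 for Cdhr3, -4.72 for Gucy1a3, -4.57 for Cd83, -4.50 for Zfp608, -4.49 for Pla2g4f, -4.41 for Igsf3, -4.35 for Gpr83 and -4.22 for Fsd1l. DESeq2 gave Cybrd1 an adjusted p of 0.0638. Among genes of Treg identity it was -2.80 for Lrrc32, -2.03 for Ikzf4, -1.89 for Foxp3, -1.31 for Ppp1r3fos and -1.25 for Il2ra, and the Il2ra call was lost when any of 6 libraries was left out, as given for each in the report. Nt5e went the other way, at 1.46. Among immediate early genes it was -3.00 for Egr2, -2.75 for Nr4a1, -2.56 for Egr3, -2.16 for Egr1 and -1.41 for Fosb. Among NF-kB genes it was -1.88 for Rel, -1.71 for Relb, -1.19 for Traf1, -1.01 for Nfkb2 and -0.96 for Icam1, and for the class II gene Cd74 it was -0.82. Among naive T cell genes it was -2.29 for Ccr7, -1.90 for Tcf7, -1.85 for Satb1, -1.54 for Actn1 and -1.47 for Igfbp4. The remaining lower genes were Arhgap20 at -3.48, Dzip1 at -2.71, Tns4 at -2.13, Adam11 at -1.95 and Nsg2 at -1.18. Which cells gave the immediate early and NF-kB transcripts was not tested.

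In the other direction, the difference was 4.21 for Mtus1, 3.47 for Il7r, 3.46 for Il9r, 3.36 for Il17rb, 3.32 for Adamts14, 3.20 for Klra1, 3.13 for Nmnat2 and 3.03 for Popdc2. Klra1 had adjusted p of 0.0674 and 0.0599 without monoclonal non-Treg replicates A and B 0.0656 without polyclonal non-Treg replicate B, 0.0565 with no filter and 0.0567 with edgeR. Nmnat2 had 0.0536 without monoclonal non-Treg replicate B, and Popdc2 had 0.0702 with limma-voom. Among effector-memory genes it was 2.57 for Ccr2, 2.46 for Lgals3, 2.35 for Maf and 1.8 for Itgb1. It was 1.96 for Ccr3 and 1.53 for App.

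By camera at the preset correlation, 9 lists differed between the 2 Treg effects. For cell cycle, 0 of 27 genes passed by limma, also when adjusted over the list alone. The median differences were 1.27 for effector-memory, 0.678 for Th1 (adjusted p = 0.00908), 0.705 for sex-linked genes (0.0128), 0.315 for the TCR complex and proximal signalling (0.00632), -0.541 for cell cycle (0.00687), -0.644 for TCR-induced early response, -0.875 for naive and quiescence, -1.01 for NF-kB targets and -1.20 for B cell markers. With an estimated correlation every adjusted p of these 9 was at least 0.289. The sex-linked list mixes Xist and Tsix with genes of the Y chromosome, so its direction does not measure sex. Its Y-linked genes were present in every library, as given below. The sex-linked call was lost without polyclonal Treg replicate B (adjusted p = 0.0717). The TCR complex list holds the 4 genes of the CD3 scaling, which that scaling pulls towards 0, so its median of -0.221 and lost call there (adjusted p = 0.135) are partly fixed by construction. The other 12 genes had a median difference of 0.269, or -0.267 after that scaling.

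The effector-memory genes had a higher Treg effect in monoclonal mice, with a median difference of 1.27 and 16 of 25 past the threshold. Their median was 1.03 in the monoclonal and -0.23 in the polyclonal Treg effect, with 7 lower and 3 higher in polyclonal Treg cells. Part of the difference therefore lies in the polyclonal mice. Scaling to the CD3 genes would remove dilution of T cell RNA in the monoclonal non-Treg libraries only if T cells of all groups held equal CD3 transcripts. That was not tested, and the other 12 TCR complex genes had a median difference of -0.267 after it. The effector-memory median was then 0.739 with an interquartile range of 0.45 to 1.22, naive genes stood at -1.41, and the calls went from 16 to 6. Under that assumption dilution is argued against as the whole cause, and without it dilution stays open. Neutrophil RNA in monoclonal Treg replicate A is argued against by a median of 1.26 without that library, with 14 genes past the threshold. Dendritic cell markers were lower in monoclonal Treg than in monoclonal non-Treg libraries, with a median of -2.07 and 7 of 9 past the threshold. Transcripts added by dendritic cells would therefore lower this difference, which argues against them as its direct source. The strain, the Rag genotype and the single receptor remain open as untested explanations. A more differentiated state of monoclonal Treg cells may underlie the pattern only as a hypothesis found in these same data.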

How the results depend on the processing

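The alternatives chosen only after the result was seen were TMM on the CPM, the pseudocounts of 0.1 and 5 CPM, CD3 scaling and leaving out genes higher in monoclonal non-Treg libraries. The test named in the design, edgeR, was also added as an alternative only then, on recovered reads. Of 217 called results of named genes, 195 kept direction and side of the threshold in every alternative run, and over 5046 alternatives of 231 results 20 changed sign, all with adjusted p above 0.05. Calls were lost for 22 results, 11 of them on leaving out a library. Of 59 list results, 8 held in every alternative and 48, these 8 included, in all but the estimated correlation, and 0 reversed in camera's direction. RLE factors, TMM, the filter of 5 CPM, both pseudocounts, thinning, DESeq2, limma-voom, edgeR and the fit without the robust step left all 6 counts within 1.5 times.

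The following counts moved further, and the cause was not tested except where fewer genes or libraries or a stricter threshold entered by construction. In a fit of only the libraries compared, 673 genes differed for the polyclonal Treg effect, 1721 between Treg groups and 4413 between non-Treg groups. Replicates differed more in the Treg than in the non-Treg groups, as given above. The shared spread of the main test may thus be too small between Treg groups and too large between non-Treg groups. With CD3 scaling the counts were 553 for the polyclonal effect, 1796 between Treg groups and 267 shared by both effects. With no filter, 756 genes differed between the effects. With a fold change of at least 2 added, the counts were 1774 for the monoclonal effect, 610 for the polyclonal effect, 1715 between Treg groups, 1481 between non-Treg groups and 284 shared. At an adjusted p under 0.01 they were 1821, 570, 1753 and 1625, with 489 for the difference of the effects and 306 shared. Leaving out genes higher in monoclonal non-Treg libraries gave 2003 for the monoclonal effect and 548 for the difference. Leaving out each library in turn, with the lone library taken to vary like the other groups, gave 1306 to 3774 for the monoclonal effect, 429 to 1231 for the polyclonal effect, 361 to 1658 for their difference, 2416 to 3583 between Treg groups, 1373 to 3227 between non-Treg groups and 267 to 642 shared. The lowest of these ranges came without a non-Treg library, except between Treg groups.

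The sign changed for Rag1 and for other fixed genes that did not pass the test. With CD3 scaling Rag1 was -0.11 in the monoclonal effect and -0.28 in the difference, the differences of Ctla4, Ikzf2 and Nrp1 were -0.14, -0.41 and -0.29, and between non-Treg groups they were 0.317, 0.162 and 0.0442. The Rag1 difference was -0.0887 with a pseudocount of 0.1 CPM, -0.88 with DESeq2, -0.92 with edgeR and -0.43 with limma-voom. Leaving out a library, Rag1 ranged from -0.31 to 0.91 in the monoclonal effect, -0.33 to 0.79 in the polyclonal effect and -0.54 to 0.68 in the difference, that of Ikzf2 from -0.0665 to 0.32 and that of Nrp1 from -0.0162 to 0.50. The cause was not tested.

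The replicate letters are shared between groups, and their block was fitted as an alternative. That block holds 1 letter effect for all 4 groups, so it cannot take up a pairing within 1 kind of mouse. Both Treg effects were tested without pairing. Deviations of same-lettered libraries correlated across genes at 0.0969 for monoclonal Treg with non-Treg and 0.0752 for polyclonal Treg with non-Treg libraries. The pairs across the mice had -0.0134, 0.0112, -0.0930 and 0.00284. These weak correlations do not tell whether Treg and non-Treg libraries of a letter shared an animal. Replicate B was above A in all 4 groups for 703 of 12881 genes, where independent groups would give 736. Of 14 stress and heat shock genes it was above A in all 4 for 5, where 0.8 would be given. Among these were Hspa1a at 15.4 and 59.4, 23.5 and 169, 19.0 and 45.7, and 32.5 and 72.4 CPM in replicates A and B of monoclonal Treg, monoclonal non-Treg, polyclonal Treg and polyclonal non-Treg cells, a gene chosen after its values were seen. Ngp, S100a9 and S100a8 were higher in A in both monoclonal groups. A difference in handling, or an animal or pool, shared by a letter is therefore not set aside for these genes. With the replicate block, 3032, 945 and 1094 genes differed for the monoclonal effect, the polyclonal effect and their difference, 2969 and 2393 between Treg and non-Treg groups, and 488 were shared.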

Other observations

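The list results in the opening paragraphs were planned, and the tests in the weighing of class II and Foxp3 transcripts were chosen only after the result was seen, as were the levels and ratios that define their genes.

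Several other gene groups moved. Th1 genes were lower in polyclonal Treg than non-Treg cells for 3 of 10 genes (4 adjusted over the list alone), with a median log2 fold change of -0.71 (camera, adjusted p = 0.000115; adjusted p = 0.0762 with an estimated correlation), while in monoclonal mice 3 were higher and 1 lower (3 and 4 adjusted over the list alone), with a median of -0.44 (camera, adjusted p = 0.806, in the direction opposite to the median). Th2 genes were higher in Treg cells, 3 of 6 with 1 lower in monoclonal (median 1.59; camera, adjusted p = 0.00169; adjusted p = 0.302 with an estimated correlation) and 4 of 6 in polyclonal mice (median 0.48; camera, adjusted p = 0.000801; adjusted p = 0.174 with an estimated correlation), or 4 with 1 lower and 5 with 1 lower adjusted over the list alone. The polyclonal Th2 call was lost with no filter (median 0.42, adjusted p = 0.101). Th17 genes went both ways, 2 higher and 3 lower of 7 in monoclonal and 3 and 3 in polyclonal Treg cells (camera, adjusted p = 0.593 and 0.706), with 2 and 5 and 3 and 3 adjusted over the list alone. Of 20 trafficking receptors, 9 were higher and 3 lower in monoclonal (10 and 4 adjusted over the list alone; camera, adjusted p = 0.0631) and 3 and 4 in polyclonal Treg cells (3 and 5; camera, adjusted p = 0.582). Of 16 glycolysis genes, 2 were higher and 0 lower by limma in polyclonal Treg cells (3 and 0 adjusted over the list alone; camera, adjusted p = 0.0131; adjusted p = 0.421 with an estimated correlation), and 2 higher and 1 lower in monoclonal ones (2 and 1; camera, adjusted p = 0.258). The glycolysis call was lost without polyclonal Treg replicate B (adjusted p = 0.566).

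Of 14 stress and heat shock genes, 2 were higher in monoclonal than in polyclonal non-Treg cells (2 with 1 lower adjusted over the list alone; camera, adjusted p = 0.849), and 5 were higher in replicate B than in A in all 4 groups. Of 10 lymphocyte development genes, 3 were higher and 1 lower in monoclonal than in polyclonal Treg cells, the same adjusted over the list alone (camera, adjusted p = 0.458). Of 5 plasma cell markers, 3 were lower there, the same adjusted over the list alone, with a median of -1.32 (camera, adjusted p = 0.0356; adjusted p = 0.267 with an estimated correlation), a call lost without monoclonal Treg replicate B (adjusted p = 0.144) or polyclonal Treg replicate B (0.166) and with no filter (0.0568). Igj lay between 60.9 and 130 CPM in the polyclonal libraries and under 1 CPM in the monoclonal ones. Of 5 CD8 T cell markers, 1 was higher and 1 lower in monoclonal Treg cells, the same adjusted over the list alone (camera, adjusted p = 0.810). Of 9 erythroid and platelet markers, 3 were higher and 1 lower there (4 and 1 adjusted over the list alone; camera, adjusted p = 0.0820), and of 5 stromal markers 1 was higher (2 adjusted over the list alone; camera, adjusted p = 0.186). Of 5 sex-linked genes, 1 was lower in monoclonal than in polyclonal non-Treg cells (3 adjusted over the list alone; camera, adjusted p = 0.0133; adjusted p = 0.265 with an estimated correlation). Xist, the transcript of the inactive X chromosome, measured 8.45 CPM in polyclonal Treg replicate A and at most 0.197 CPM in every other library. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d lay between 44.2 and 234 CPM in every library.

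Further lists passed at the preset correlation in comparisons where their members were not described. In monoclonal Treg cells, 10 of 16 IL-2 and STAT5 targets were higher and 3 lower (10 and 4 adjusted over the list alone; camera, adjusted p = 0.00131; adjusted p = 0.425 with an estimated correlation). There, 7 of 26 type I interferon genes were lower and 1 higher (9 and 1 adjusted over the list alone; camera, adjusted p = 0.0278; adjusted p = 0.473 with an estimated correlation), next to the fall of dendritic cell markers, and the call was lost without monoclonal Treg replicate B (adjusted p = 0.102) or monoclonal non-Treg replicate B (0.0506). Of 27 cell cycle genes, 0 passed in monoclonal Treg cells by limma. In polyclonal Treg cells, 6 of 23 early response genes were higher and 3 lower (10 and 4 adjusted over the list alone; camera, adjusted p = 0.0318; adjusted p = 0.421 with an estimated correlation), a call lost without polyclonal Treg replicate B (adjusted p = 0.267) or polyclonal non-Treg replicate B (0.239). There, 4 of 16 TCR complex genes were lower and 1 higher, the same adjusted over the list alone (camera, adjusted p = 0.0126; adjusted p = 0.397 with an estimated correlation), a call lost without polyclonal Treg replicate A (adjusted p = 0.147) and after CD3 scaling (0.0900), which uses 4 of these genes. Of 13 B cell list genes, 6 were lower and 1 higher (6 and 2 adjusted over the list alone; camera, adjusted p = 0.00505; adjusted p = 0.424 with an estimated correlation).

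Between Treg groups, 10 of 18 co-inhibitory and anergy genes were lower in monoclonal mice and 2 higher (11 and 3 adjusted over the list alone; camera, adjusted p = 0.0104), a call lost without monoclonal Treg replicate B (adjusted p = 0.0551). Treg-repressed genes were lower for 10 of 16 and higher for 2 (10 and 3 adjusted over the list alone; camera, adjusted p = 0.00126), and TCR complex genes lower for 7 of 16, the same adjusted over the list alone (camera, adjusted p = 0.00511). B cell list genes were higher for 6 of 13 and lower for 1 (6 and 2 adjusted over the list alone; camera, adjusted p = 7.58e-05). Type I interferon genes were higher for 6 of 26 and lower for 1 (7 and 1 adjusted over the list alone; camera, adjusted p = 0.0286), a call lost without monoclonal Treg replicate A (adjusted p = 0.153) or polyclonal Treg replicate A (0.164). Between non-Treg groups, 5 of 9 NK cell markers were higher in monoclonal mice, the same adjusted over the list alone (camera, adjusted p = 0.000157; adjusted p = 0.0948 with an estimated correlation). Of 16 Treg-repressed genes, 7 were lower and 3 higher (8 and 3 adjusted over the list alone; camera, adjusted p = 0.0171). The median of 27 cell cycle genes was -0.31 and 0.17 after CD3 scaling, with 1 gene lower, the same adjusted over the list alone (camera, adjusted p = 0.0219). None of the lists in this paragraph had an adjusted p under 0.0872 with an estimated correlation.

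Class II transcripts stood out in the monoclonal libraries, where 140 genes were above 50 CPM and over 20 times their polyclonal non-Treg level in non-Treg replicate A and 161 in replicate B. Measured against the replicate on which they were not chosen, these genes had median log2 fold changes of -1.99 and -1.79 in monoclonal Treg cells, and the other genes above 50 CPM had -0.00596 and -0.0317. Class II genes switched on in T cells with no other cell present are argued against by a median of 4.41 for the fixed dendritic cell list, and B cell RNA by the 1.16 CPM that the highest of Cd79a, Ms4a1 and Pax5 reached in a monoclonal library, next to 8497 CPM for Cd74. RNA of dendritic cells in the sorted fractions is a candidate source, since 8 of the 9 markers were higher in monoclonal non-Treg cells, 2 of the 9 (Ccr9 and Itgax) also standing in other lists. Of 20 myeloid markers, 13 were higher there too, with a median of 3.35, so these counts do not single out dendritic cells. A CD4+ gate would remove cells without CD4, and some spleen dendritic cells carry CD4, so the strain and the Rag genotype, which change how many lymphocytes a spleen holds, stay open as untested reasons for the difference.

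Foxp3 transcripts in monoclonal non-Treg libraries reached 0.135 of the Treg level, against 0.0359 in polyclonal mice. Treg cells carried into the negative fraction could account for this, since genes restricted to Treg cells in polyclonal mice (ratio under 0.067, at least 20 CPM in both Treg groups) had a median monoclonal ratio of 0.178, but only 4 genes met that limit: Src at 0.214, Il2ra at 0.140, Ikzf4 at 0.235 and Ppp1r3fos at 0.141. Foxp3 transcribed in non-Treg cells without the other Treg genes would keep those ratios under 0.067 in median, and their lower quartile was 0.141. Of genes with at least 20 CPM in Treg cells, 0 in monoclonal and 11 in polyclonal mice lay under that limit. Any set of such genes would have given the same outcome in monoclonal mice, so the ratios do not decide on this explanation. The lowest monoclonal ratio, 0.0859 for Rln3, lies below that of Foxp3, so carried-over cells need not be the whole source. An effect of strain, Rag genotype or receptor on Foxp3 in the negative fraction cannot be told apart from this, because the log2 fold change of 2.10 between the non-Treg groups is what each would give.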
